A study of Macrobrachium nipponense with 6 samples.

How the data were processed

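Total RNA of pooled gill, hepatopancreas, muscle and hemocytes was labelled with Cy3 and hybridised to single-colour miRNA arrays of LC Sciences, 1 array per sample, per the labels. The deposited scanner tables hold the median intensity of each spot on a linear scale, with no local background and no normalization, as the values of empty spots show. The deposited value table holds intensity values that the authors subtracted and scaled between arrays. The scaling method is not given in the sources used here. On bright probes these values followed the scanner values closely (log2 r from 0.994 to 0.999 per array), times factors with medians from 0.649 to 1.52, which is why they were read as linear. Their medians were 4.37, 4.11 and 6.44 on normoxia 1 to 3 and 5.89, 0.0400 and 2.95 on hypoxia 1 to 3. They served as an alternative. Columns of samples outside this series were 0.

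Each array had 3968 spots, of which 2546 were miRNA probes with 1 spot each, 1130 were empty, 268 were added calibration probes and 24 targeted a zebrafish 5S RNA. The background of a spot was the median of its 20 nearest empty spots. Background was corrected with normexp (limma, offset 50), which shrinks changes of dim probes. Control spots were then left out, arrays were quantile normalized, and log2 was taken. A probe counted as detected when it lay more than 3 standard deviations of the empty spots above its background. A planned limit on the variation between a probe's own spots could not be applied, because each probe had 1 spot.

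Groups were taken from the sample titles. Probes detected on all 3 arrays of at least 1 group were tested with limma (lmFit and eBayes, hypoxia minus normoxia, version 3.58.1 in R 4.3.3), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Lists were compared with the other tested probes by camera with an estimated correlation, and again with a preset correlation of 0.01, and adjusted over the 14 lists tested. As a further alternative fry tested each list against no change, without the other probes. The lists covered hypoxia-linked, muscle, nervous system, vertebrate blood and liver, metabolism and immune miRNAs, 9 families or clusters, predicted probes and passenger strands.

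Named probes followed a rule fixed before the data were examined. It took the largest changes past the threshold or, with fewer than 10 past it, the probes with the smallest unadjusted p up to 10, 1 per stem and arm. It also took the brightest tested probe of up to 4 stems of each list, miR-210, and probes detected in 1 group only. A fold against a group below the detection limit used a stand-in signal on each array of that group. The stand-in was the higher of the lowest detected signal and the probe's own. Such a fold is a lower bound for the measured means only and leaves out their sampling error.

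The procedure was tested on simulated arrays made from the measured means and spreads, with 60 changed probes in each of 20 runs and about 354 probes tested. At the observed spread it found 21.0% of 2-fold, 67.0% of 4-fold and 81.5% of 8-fold changes. Of its calls, 6.63% were false and 0 had the wrong sign, and fitted changes were 0.83 of the true log2 change. At 0.5 times that spread 12.5% of calls were false. Noise was drawn independently for each probe and array, while in the data the first principal component held 38.1% of the variance (below). These rates therefore do not cover differences that probes share, and they hold for 60 changed probes. In a simulation with independent noise over 339 probes, a shift of 0.6 (log2) in a list of 16 probes was called in 4 of 20 runs with an estimated correlation and in 19 of 20 with the preset one. With no shift, neither called it in any of the 20 runs. Independent noise is close to what the preset test assumes, so these runs do not show how it behaves on correlated probes. In the data the estimated correlation was 0.197 for the miR-9 and miR-79 family and 0.0948 for the miR-34, miR-277 and miR-317 cluster. With the shift, the preset test also called another list in 8 runs; some lists share probes with the shifted one.

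Alternatives covered background correction, scaling, filtering, the spread model, array weights, a replicate block, single arrays left out and detection limits. Figures were drawn with matplotlib 3.10.9.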

Results

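MicroRNA levels were measured in the oriental river prawn, Macrobrachium nipponense, a freshwater decapod, kept for 24 h at normal or low dissolved oxygen. Normoxic water held 6.5 ± 0.2 mg O2 per L and hypoxic water 2.0 ± 0.1 mg O2 per L. Each of the 6 samples was a pool of gill, hepatopancreas, muscle and hemocytes, so a value is a level over the pooled tissues, and 3 samples came from each oxygen level. The labels number the samples within a group and do not say whether they came from separate animals, so p-values measure the spread between these samples. Each array carried 2546 miRNA probes with 2546 distinct target sequences, named after miRNAs of other arthropods or after predicted precursors. The probe names are printed as the array gives them. Positions in the prawn genome were not analysed here.

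Detection differed widely between single arrays. Normoxia 1, 2 and 3 had 545, 1001 and 342 probes above the detection limit, and hypoxia 1, 2 and 3 had 443, 908 and 420. The limit, 3 standard deviations of empty spots above the local background, ranged from 27.8 on hypoxia 2 to 94.5 on normoxia 3. On all 6 arrays 292 probes were detected, and 1007 were detected on none. The 339 probes detected on all 3 arrays of at least 1 group entered the comparison, and the number of arrays limits its precision.

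The first comparison asked which miRNAs differed in level after 24 h of low oxygen. No probe passed: of 339, 0 were higher and 0 lower in hypoxia at the adjusted p threshold of 0.05 (limma, smallest adjusted p = 0.702). At an unadjusted p under 0.05 there were 16 probes, 6 higher and 10 lower, where chance alone gives 16.95. The number was 63 (34 higher, 29 lower) without hypoxia 3, 73 (37 and 36) with array weights, 6 (4 and 2) without normoxia 2 and 15 (10 and 5) after cyclic loess scaling. Between the groups, 312 probes (92.0%) differed by less than 2-fold, 18 were at least 2-fold higher in hypoxia and 9 at least 2-fold lower. Some of these changes rested on 1 array, with examples chosen after seeing the data. The probe bmo-miR-276-3p, at 2.63 (log2), read 6.78 on normoxia 1 beside 14.49 and 14.42 on normoxia 2 and 3. At -1.59, api-bantam read 7.32 on hypoxia 1 beside 13.32 and 12.98 on hypoxia 2 and 3. The 3 values of each group did not overlap for 34 of the 339 probes, and chance gives 10% with 3 against 3. The median standard error of a change was 0.39 (log2), and the median 95% confidence interval reached 0.94 to either side. A change of about 2-fold was therefore within the interval of many single probes, and an absent call does not show an equal level. Leaving out hypoxia 3 gave 1 probe past the threshold, tur-miR-281-5p, at 2.46 (log2) higher in hypoxia with an adjusted p of 0.0120 (limma). That fit keeps hypoxia 1 and 2, the arrays with the highest calibration ratio (below), so oxygen level and that ratio cannot be told apart in it. The probe aae-miR-281-5p, 4 edits away in sequence, was 3.98 (log2) brighter and changed by 0.11 over the 6 arrays. Of 18 tested miR-281 probes, 9 lay above 0 and 9 below.

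**Figure D1:**
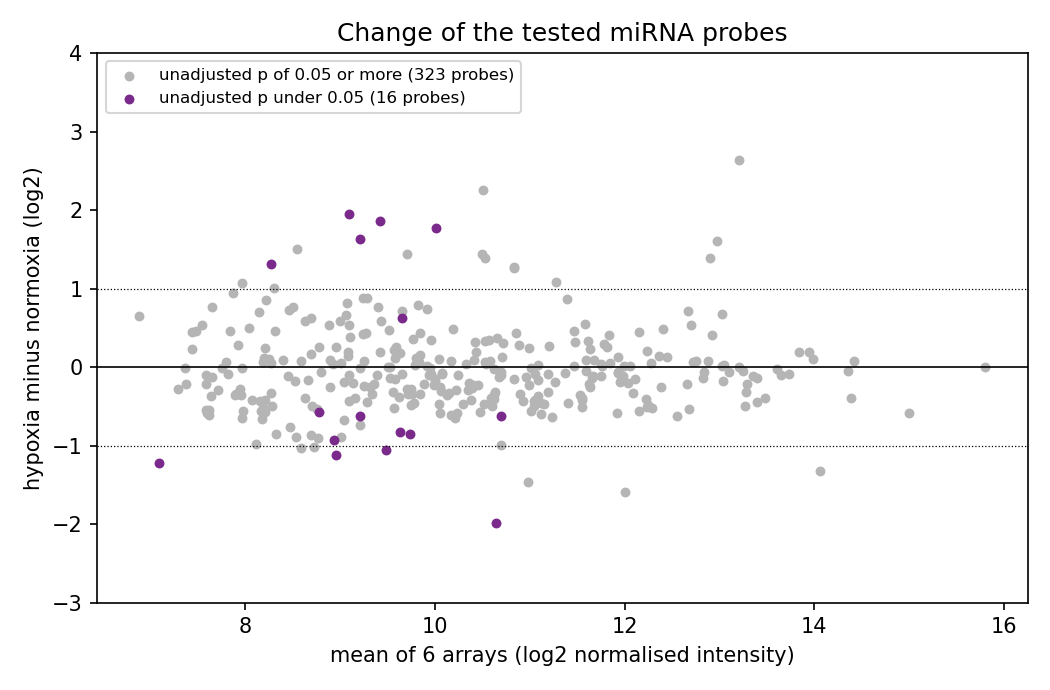
Change of the 339 tested probes (hypoxia minus normoxia, log2, vertical axis) against the mean of the 6 arrays (log2 normalised intensity, horizontal axis). Purple points are the 16 probes with an unadjusted p under 0.05, dotted lines mark 2-fold, and no probe passed the adjusted threshold.

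The 10 probes with the smallest unadjusted p, taking 1 per stem and arm, are given as values, since none passed the adjusted test (limma, adjusted p = 0.702 to 0.824). The probe dan-miR-2b_L-2_1ss3TG measured 7.62 ± 0.46 (log2, SD, n = 3) in normoxia and 8.93 ± 0.13 in hypoxia. For dsi-miR-305_R-3_1ss14AG the means were 8.12 ± 0.97 and 10.07 ± 0.47, and for hme-miR-9b 8.39 ± 0.46 and 10.02 ± 0.81. Values of tca-miR-9e-5p were 8.49 ± 1.22 in normoxia and 10.35 ± 0.42 in hypoxia, and those of tca-miR-252a-5p 9.34 ± 0.04 and 9.97 ± 0.18. The probe tur-miR-281-5p read 11.65 on hypoxia 1 and 11.52 on hypoxia 2 but 9.52 on hypoxia 3, against 9.12 ± 0.06 in normoxia. Lower means in hypoxia were measured for api-miR-184b (10.01 ± 0.26 and 8.96 ± 0.12), aae-miR-34-5p_R+1 (10.16 ± 0.24 and 9.31 ± 0.14) and dpu-miR-307_R+1 (10.04 ± 0.12 and 9.22 ± 0.23). Near dsi-miR-305_R-3_1ss14AG, at 3 edits, cqu-miR-305-5p was 4.01 (log2) brighter and changed by -0.07. Near dan-miR-2b_L-2_1ss3TG, at 3 edits, bmo-mir-2a-1-p3_1ss1TG was 3.48 brighter and changed by -0.12. Brighter probes 2 edits from hme-miR-9b and api-miR-184b changed in the same direction as these, by 0.41 and -0.41. The change of each of the 10 kept its sign under every alternative that gave a value for it. The groups do not overlap in any of the 10, so leaving out a single array could not turn a sign. With single arrays left out only tca-miR-9e-5p moved by more than 1.5 times, from 1.86 to 1.22 without normoxia 2.

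**Figure D2:**
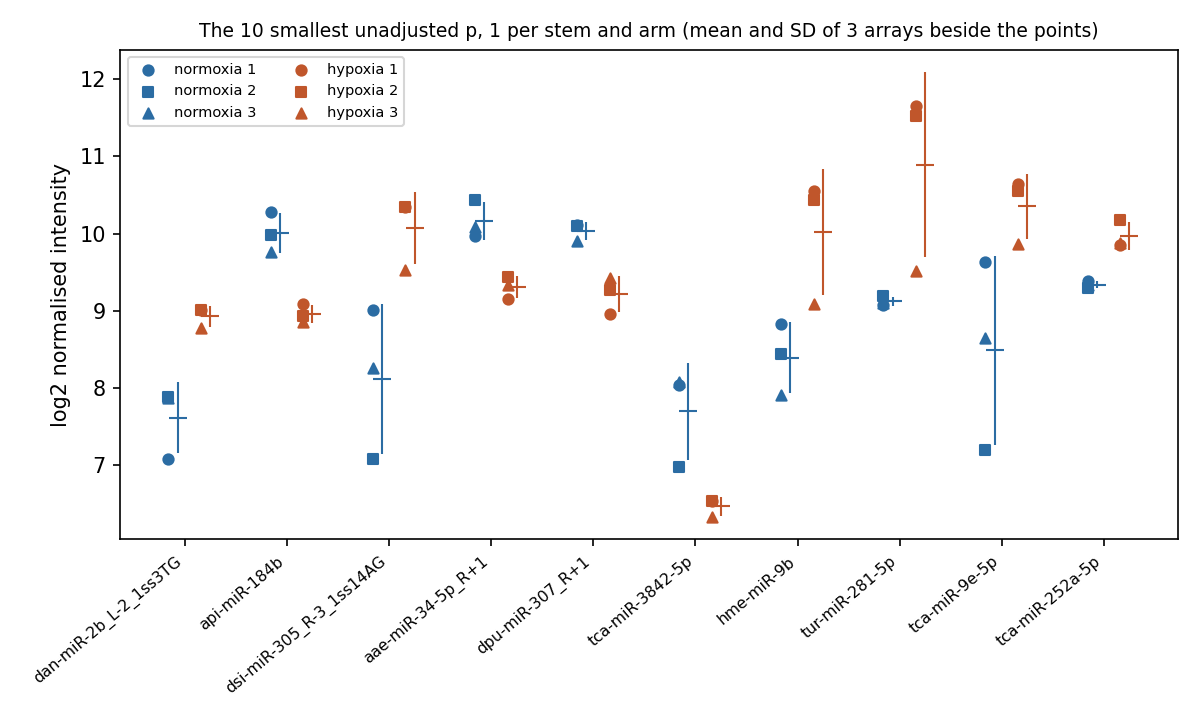
Log2 normalised intensity on each array of the 10 probes with the smallest unadjusted p, taking 1 per stem and arm (normoxia blue, hypoxia orange; circles, squares and triangles are replicates 1, 2 and 3), with the mean and SD of 3 arrays beside them. The groups do not overlap in any of the 10, and hypoxia 3 lies at 9.52 for tur-miR-281-5p where hypoxia 1 and 2 lie at 11.65 and 11.52.

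The second comparison asked which miRNAs were detected at 1 oxygen level only. One probe, tca-miR-3842-5p, was detected on all 3 normoxia arrays and on 0 of the 3 hypoxia arrays, and 0 probes showed the opposite. Its mean was 7.70 ± 0.62 (log2, SD, n = 3) in normoxia against 6.47 ± 0.12 measured in hypoxia. It was not above the detection limit there. Against the stand-in for signals below that limit, the normoxia mean was 1.70-fold higher, a value that leaves out sampling error. The measured change, hypoxia minus normoxia, was -1.23 (log2, confidence interval -2.10 to -0.35) and did not pass (limma, adjusted p = 0.702). A split of 3 against 0 cannot go below a two-sided p of 0.1 in Fisher's exact test. At a limit of 2 standard deviations, and in the authors' values, this probe no longer met the rule. It was also lost with a robust standard deviation of the empty spots, chosen after seeing the data, which gave 0 probes in normoxia only and 14 in hypoxia only.

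Of the 17 miRNA lists fixed before the data were examined, 14 had at least 3 tested probes, and none passed the test against the other probes with an estimated correlation (camera, smallest adjusted p = 0.520). In each of the 14, 0 members passed adjusted over the list alone, and 0 passed over all 339 probes. Probes of a list often target near-identical sequences, so they are not independent of each other. The medians of the let-7, miR-8, Hox cluster, miR-279 and immune lists changed sign under at least 1 of 4 other scalings. Of the 29 probes named as examples of the lists, 28 moved by more than 1.5 times or changed sign when some single array was left out, and 21 changed sign, so their changes are given as values only.

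The miR-9 and miR-79 family, known from insect nervous system development, had 14 of 16 tested probes above 0 and a median change of 0.50 (log2). It passed with a preset correlation of 0.01 (camera, adjusted p = 0.000176) and did not with an estimated correlation (adjusted p = 0.520). The brightest probe of each stem was tca-miR-9a-5p, at 0.41 (95% interval -0.13 to 0.94), and bmo-miR-79-3p, at 0.54 (-1.13 to 2.20). Averaged over the 16 probes, hypoxia 1 and 2 read 10.74 and 10.63, and hypoxia 3 read 9.71, beside 9.79 ± 0.11 (SD, n = 3) in normoxia. That value of hypoxia 3 averages opposite moves: 8 of the 12 miR-9 probes lay above every normoxia array there, and 3 miR-9 probes and all 4 miR-79 probes below every one. The miR-9 probes include names of both the 5p and the 3p arm, which are different sequences. On hypoxia 3, tca-miR-9a-5p read 12.04, above every normoxia array, and dpu-miR-9-3p_R-1 read 10.12, below every one. The 5p probes tca-miR-9c-5p and tca-miR-9e-5p also read above every normoxia array on hypoxia 3, at 11.75 and 9.87. Named for the 3p arm, bmo-miR-79-3p read 7.59 there, below every one. In these probes the moves went with the arm, which was not tested over all 16.

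In the cluster of miR-34, miR-277 and miR-317, encoded together in flies, 16 of 18 tested probes lay below 0, with a median of -0.39. All 18 were miR-34 or miR-317 probes, and no miR-277 probe was tested. This list also passed with the preset correlation (adjusted p = 0.00681) and not with an estimated correlation (adjusted p = 0.520). On hypoxia 3, 5 of its 8 miR-34 probes lay above every normoxia array and the other 3 below. Its examples were tur-miR-34-5p at -0.33 (-1.34 to 0.67) and ame-miR-317 at -0.09 (-0.75 to 0.56). In the miR-92 and miR-25 seed family 10 of 13 probes lay below 0, with a median of -0.43, or -0.19 after cyclic loess scaling (adjusted p = 0.865, and 0.0915 with the preset correlation); tca-miR-92a-3p was at 0.16 and dan-miR-311b_R-2_1ss9AT at 0.04.

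Muscle miRNAs had 3 of 5 tested probes above 0 (adjusted p = 0.865). Among them dme-miR-1-3p, a miRNA of muscle in many animals, was at 0.41 (-0.77 to 1.59) but at -0.05 without normoxia 3, and hme-miR-133 at -0.17 (-1.36 to 1.03). Nervous system miRNAs were listed to check for nerve tissue carried along. Only miR-9, miR-263 and miR-7 had tested probes, so the list cannot show whether such tissue was present. Of its 34 tested probes, 12 lay above 0 (camera, adjusted p = 0.865). Their median was -0.14 while their mean was 0.06. Examples were dme-miR-263a-5p at -0.08 and aae-miR-7_R+1 at -0.0088. The list shares its miR-9 probes with the family above.

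Of the let-7, miR-100 and miR-125 cluster, linked to developmental timing in insects, 9 of 21 probes lay above 0 (adjusted p = 0.865). The abundant dme-let-7-5p was at -0.14 (-0.75 to 0.47), api-miR-100 at 0.20 and ame-miR-125 at 1.28 (-0.78 to 3.33), or 0.41 without normoxia 3. The median of this list was -0.02, its mean 0.22 and its test direction up. In the miR-2, miR-13 and miR-71 list 21 of 46 probes lay above 0 (adjusted p = 0.865), with bmo-mir-2a-1-p3_1ss1TG at -0.12, api-miR-13a at 0.13 and tca-miR-71-5p at 0.14. Median and mean were below 0 there, at -0.10 and -0.04, and the test direction was up.

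Arthropod metabolism miRNAs had 13 of 20 probes above 0 (adjusted p = 0.520), with a median of 0.06 and a mean of 0.40. The brightest, cqu-miR-305-5p, was at -0.07 (-0.72 to 0.58), aga-miR-275_1ss13AT at -0.62 (-1.49 to 0.25) and aae-miR-278-3p_1ss12TC at 0.46. Of the miR-8 and miR-200 family, which acts on insulin signalling in the fly fat body, 2 of 5 probes lay above 0 (camera, adjusted p = 0.865) and dpu-miR-8_R-1 was at 0.02 (-0.98 to 1.02). All 5 were miR-8 probes. The bantam family, a growth regulator in flies, had 2 of 4 probes above 0 (adjusted p = 0.865), with ame-bantam at -0.05 (-0.70 to 0.60). Its mean was -0.02 and its median 0.0050.

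Hox cluster miRNAs, tested with miR-10 probes only, had 4 of 9 above 0 (camera, adjusted p = 0.865), and tur-miR-10-5p was at 0.09. The miR-279 and miR-996 seed family, tested with miR-279 probes only, also had 4 of 9 above 0 (camera, adjusted p = 0.865). There bmo-miR-279a_R+3_1ss17CT was at -0.14, the median at -0.11 and the mean at 0.18. Crustacean immune miRNAs, the largest list, had 44 of 93 probes above 0 (adjusted p = 0.865), with smr-miR-965 at 0.02 and tca-miR-12-5p at 0.08. Its median was -0.0088 and its mean 0.03. Of the predicted probes 4 of 9 lay above 0 (adjusted p = 0.865); PC-5p-2388_431 was at -1.46 (-3.22 to 0.30), PC-5p-14110_76 at 0.76, PC-5p-16770_62 at -0.58 and PC-3p-189091_4 at -0.18. Without normoxia 1, PC-5p-2388_431 was at -0.75 and PC-5p-16770_62 at 0.36. Their mean was -0.13 and the test direction was up.

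**Figure D3:**
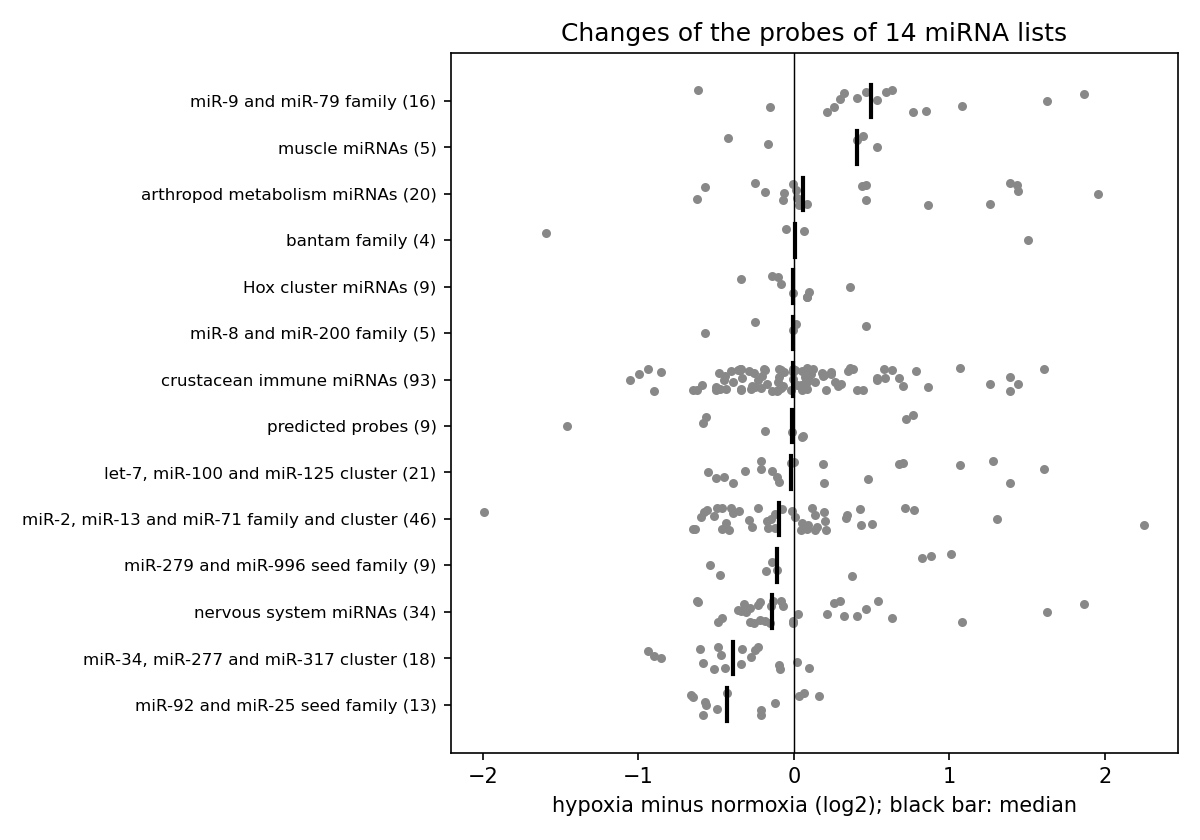
Change of each tested probe (hypoxia minus normoxia, log2, horizontal axis) in the 14 lists with tested members, the number of probes in brackets and the median as a black bar. The medians run from -0.43 in the miR-92 and miR-25 seed family (-0.19 after cyclic loess scaling) to 0.50 in the miR-9 and miR-79 family, and no list passed with an estimated correlation.

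The remaining 3 lists gave no test. The list of hypoxia-linked miRNAs of vertebrate studies was represented by 18 probes, all for miR-210, a miRNA induced by low oxygen in mammals. None of them was detected on more than 3 arrays and 6 were detected on none; the brightest reading was 208 above background. On normoxia 1, 2 and 3 the limit was passed by 1, 8 and 0 of them, and on hypoxia 1, 2 and 3 by 1, 4 and 2. A difference in miR-210 was thus not measurable on these arrays. The vertebrate blood and liver list and the passenger strand list matched 0 probes.

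Agreement differed between pairs of arrays. Across the 339 probes, which are not independent replicates, Pearson's r averaged 0.855 within normoxia, 0.803 within hypoxia and 0.837 between the groups. The lowest value within a group was 0.735, between hypoxia 1 and hypoxia 3, and hypoxia 2 and hypoxia 3 gave 0.778. Hypoxia 1 and hypoxia 2 gave 0.895, the highest of all pairs, so the lower mean within hypoxia came from hypoxia 3. The first principal component held 38.1% of the variance; it placed hypoxia 1 and 2 at 10.9 and 6.87, hypoxia 3 at -14.3 and the normoxia arrays at -3.44, -0.298 and 0.213. The added calibration probes named 3M gave 11.9% and 8.60% of the signal of those named 3P on hypoxia 1 and 2 and 1.13% on hypoxia 3, beside 2.57%, 3.71% and 1.81% on the normoxia arrays. The files do not state what 3M and 3P stand for.

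**Figure D4:**
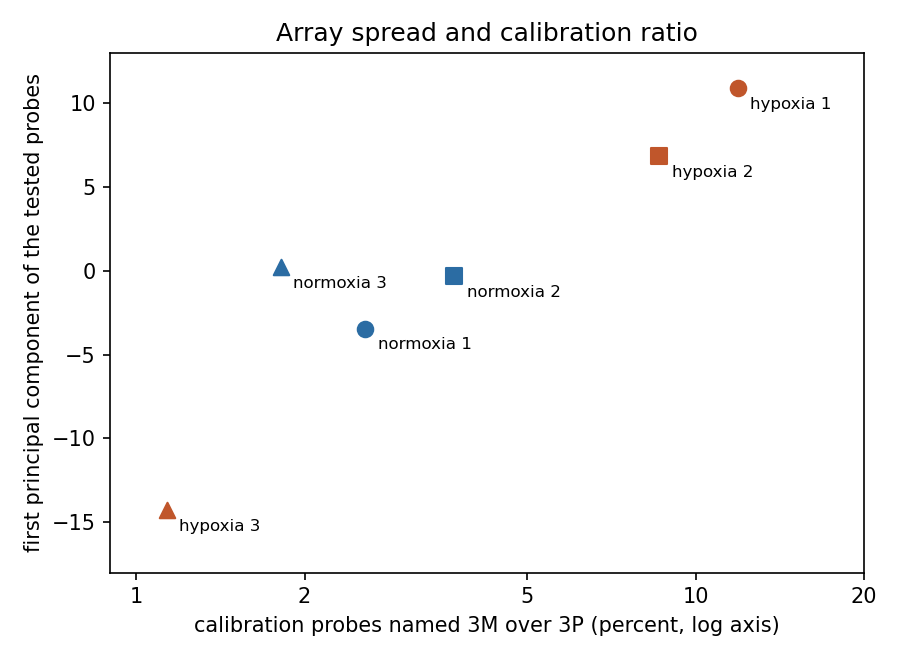
First principal component of the 339 probes (vertical axis, log2 units) against the signal of calibration probes named 3M as a percent of those named 3P (horizontal log axis), 1 point per array (normoxia blue, hypoxia orange). Hypoxia 1 and 2 lie at the upper right, at 11.9% and 8.60%, and hypoxia 3 at the lower left, at 1.13%.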

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

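The tests in this part were all chosen after the result was seen. The signal of calibration probes named 3M, as a percent of those named 3P, was 11.9% on hypoxia 1 and 8.60% on hypoxia 2, above the highest normoxia array at 3.71%. These probes are outside the miRNA comparison. The names are read here as mismatched and matched probes, which the files do not state; a second calibration pair, PUC2MM over PUC2PM, gave 54.8% and 32.9% on these arrays, 13.3% on hypoxia 3 and 16.1% to 23.9% in normoxia. For the difference of group means of the log2 ratio, an exact permutation test gave a two-sided p of 0.4 (n = 3 per group), where the smallest possible is 0.1.

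The log2 ratio followed the first principal component over the 6 arrays (r = 0.922, exact permutation p = 0.00972; rho = 0.829, exact permutation p = 0.0583; 2 relations computed, adjusted p = 0.00972 and 0.0583). Without hypoxia 1 and 2, r was 0.777 over 4 arrays (exact permutation p = 0.25, a test with little power), so the relation past the threshold rests on those arrays. Oxygen level accounted for 2.17% of the variance of this component, and GC content of the targets correlated with its loadings at rho = 0.0565 across probes, which argue against both as its main source. A candidate explanation is hybridisation specificity that differed between arrays. The test compared 50 dim probes that had a near-identical probe at least 4 times as bright with 60 others. Those 60 lay in the same range of brightness and had no brighter near-identical probe. Probes whose near-identical probe was brighter by less were left out, and related probes are not independent. The median rise of the 50 with the log2 ratio was 0.67 more per unit than that of the 60 (permutation p = 1e-05, the smallest that 100000 resamples can give). That difference was above 0 in 12 of 12 settings of the similarity and brightness limits (0.43 to 0.75), and what made the arrays differ stays open.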

How the results depend on the processing

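Alternatives by stem and arm, with the log2 calibration ratio as a covariate and with a robust background deviation were chosen after seeing the data. The count of changed probes (limma) was 0 in all alternatives except without hypoxia 3; single arrays left out gave 0 to 1. Array weights, which gave hypoxia 3 a weight of 0.168, left 0 probes with a smallest adjusted p of 0.0547, and over all alternatives the smallest ranged from 0.0120 to 1.00. The number at an unadjusted p under 0.05 was 5 with the 75th percentile or no scaling, 7 of 162 by stem and arm, 44 with the covariate, 72 over all 2546 probes, 73 with array weights, and 6 to 63 with single arrays left out (6 without normoxia 2, 9 without normoxia 3, 63 without hypoxia 3). Same-numbered samples did not deviate together (r = -0.25, -0.27 and -0.06) and no sample correlated best with its own number; the replicate block left 0 changed probes, 11 at an unadjusted p under 0.05, and changed no list call.

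With the preset correlation the shifts against other probes of the miR-9 and miR-79 family (0.63) and the miR-34, miR-277 and miR-317 cluster (-0.40) passed; neither did with an estimated correlation (adjusted p = 0.520 for both). Shifts that changed sign were never past the threshold: the miR-8 and miR-200 family was at 0.11 in the authors' values and 0.082 with cyclic loess against -0.04, and the miR-279 and miR-996 family at -0.28 with the covariate against 0.22. With single arrays left out, shifts ran from -0.23 to 0.43 for muscle, -0.0426 to 0.22 for nervous system, -0.13 to 0.11 for miR-2, miR-13 and miR-71, -0.24 to 0.17 for miR-8 and miR-200, -0.15 to 0.20 for Hox cluster, -0.43 to 0.47 for bantam, -0.24 to 0.82 for miR-279 and miR-996, -0.0065 to 0.14 for immune and -0.29 to 0.0200 for predicted probes. Signs held at 0.27 to 0.62 for metabolism, 0.13 to 0.36 for let-7, 0.45 to 0.93 for miR-9, -0.46 to -0.22 for miR-92 and -0.50 to -0.29 for the miR-34 list. Of 168 list alternatives 145 kept direction and side of the threshold. The cause was not tested.

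Probes detected in normoxia only and hypoxia only numbered 1 and 1 at 2 standard deviations, 35 and 30 when 2 of 3 arrays sufficed, 39 and 11 in the authors' values and 0 and 14 with the robust deviation. With single arrays left out they ran from 1 to 32 and from 0 to 16; fewer arrays make the rule easier to meet. Detection limits differed between arrays, and their part in these counts was not tested. The limit alone did not order the arrays: normoxia 2, at 67.6, had 1001 probes detected and normoxia 1, at 35.6, had 545. Of 739 values of 39 named probes under alternatives, 66 changed sign, 0 of them among the 10 chosen by p. The scan-run block was not run: the labels give no batch, and the deposited names set only normoxia 1 apart by another run number, so a block would equal leaving it out (0 changed probes, 20 at an unadjusted p under 0.05); with 1 spot and 1 sequence per probe, averaging either would change nothing.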

Other observations

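Apart from the planned counts over other splits of the arrays, the tests in this part were chosen after the result was seen. Detection differed with the kind of probe name. Of 185 probes whose names carry a suffix after the miRNA name, 108 (58.4%) were detected on all 6 arrays, against 178 of 2297 plain names (7.75%) and 6 of 64 predicted probes (9.38%). The suffixed share exceeded the plain share (Fisher's exact test, two-sided p = 1.74e-60; probes are not independent).

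Of 33 miRNA families with at least 3 tested probes, 8 had the mean changes of all their tested probes on 1 side of 0, though no probe passed. With each array left out in turn, all probes kept their side only in miR-307 (6 of 6 below 0) and miR-79 (4 of 4 above 0). The miR-307 median ran from -1.24 to -0.53 over these and was -0.66 after cyclic loess scaling. The miR-79 median, 0.68, ran from 0.24 to 1.41 and was 1.02 after that scaling. On hypoxia 3 alone, however, all 4 miR-79 probes lay below every normoxia array. Of miR-34 (8 of 8 below 0, median -0.39) at least 7 kept their side and of miR-193 (5 of 5 below 0, median -0.39) at least 4, with medians from -0.76 to -0.24 and from -0.91 to -0.21. The other 4 rested on single arrays. The miR-1 median of 0.45 became -0.05 without normoxia 3, with 0 of 3 probes above 0, and the miR-2788 median of 0.88 became -0.46 without hypoxia 3, with 1 of 3 above 0. The miR-7 median of -0.0088 became 0.07 without normoxia 3 and -0.27 with no scaling. The 6 let-7 probes, all below 0 at a median of -0.18, had 2 below 0 without hypoxia 2, after 75th percentile scaling and in the authors' values.

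The 16 miR-9 and miR-79 probes averaged 0.57 (log2, SE 0.33) above normoxia; hypoxia 1 and 2 were high, and on hypoxia 3, 8 of the 16 lay above every normoxia array and 7, with all 4 miR-79 probes, below every one. With the log2 calibration ratio as a covariate the shift was 0.30 (SE 0.07), 52.1% of its size. Split after that value was seen, it went from 0.53 to 0.37 for 12 miR-9 probes and from 0.68 to 0.08 for 4 miR-79 probes. The 12 miR-9 probes pool names of the 5p and the 3p arm. The pooled shift of 0.30 lies within 1 standard error of the bound of 0.29 set for this test, whose reading was made stricter after the value was seen. The intervals of the 16 and of the 12 probes exclude 0, and that of the 4 does not. Hybridisation specificity may thus account for part of the pooled shift, or for all of it in the miR-79 probes. It stays open beside oxygen level. Of the 6 probes higher at an unadjusted p under 0.05, 5 had a near-identical probe at least 4 times as bright, against 1 of the 10 lower ones and 14.7% of all tested. The 10 splits of the 6 arrays are too few for a share under 0.05; the real shift against the other probes was 0.63, the highest other 0.69, and 3 splits reached the real value.

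The miR-34 and miR-307 probes lay below normoxia on average but differed on hypoxia 3. The 8 miR-34 probes averaged 9.16, 9.18 and 9.62 on hypoxia 1 to 3 and 9.64, 10.12 and 9.82 in normoxia, and on hypoxia 3, 5 of them lay above every normoxia array and 3 below; the 6 miR-307 probes averaged 8.64, 8.63 and 7.44, beside 8.79, 9.50 and 9.34, and their shift of -0.97 (SE 0.45) was -0.58 without hypoxia 3. With the log2 calibration ratio as a covariate the miR-34 shift went from -0.54 (SE 0.21) to -0.44 (SE 0.21, 95% interval ± 0.66), which leaves hybridisation specificity open, and the miR-307 shift to -1.30 (SE 0.28, 95% interval ± 0.88), which argues against it as the whole source there, as far as this ratio measures it. For both families 1 of the 10 splits, the real one, reached the real size (0.54 against 0.53 as the highest other for miR-34, and 0.97 against 0.87 for miR-307), and 10 splits are too few for a share under 0.05. The families were picked from the 33 for their direction and their probes target near-identical sequences, so oxygen level, differences between the pooled samples and chance stay open.

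For the count of changed probes, all 10 splits gave 0, the real value and the highest other. At an unadjusted p under 0.05 the real split gave 16 probes, 5 of the 10 splits gave as many, and the highest other gave 41. That other split set hypoxia 3 with normoxia 1 and 2, against hypoxia 1 and 2 with normoxia 3. It was picked for its count and keeps hypoxia 1 and 2 together, so it cannot separate oxygen level from other differences between the arrays. For neither count do 10 splits allow a share under 0.05.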
